A study of Mus musculus with 8 samples.

How the data were processed

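Mammary cells of 10-week-old wild-type and BK5.IGF-1 ICR mice were profiled on the C1 platform (3 samples per genotype) and on the 10X platform (1 sample per genotype). Per the labels' protocols, cells came from enzymatically dissociated abdominal and inguinal glands and were sorted by flow cytometry before the 10X run, and the C1 libraries were made with Nextera XT. Per the submitters' processing notes, FastQC, STAR 2.5.3a, HTSeq and DESeq2 were used for the C1 data and Cell Ranger 3.1.0, Seurat and DESeq2 for the 10X data, with the mm10 genome. The roles of these tools are not given in the sources used here.

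The deposited C1 tables hold log2 values of counts that the authors had normalized and transformed, 1 column per cell. All values share 1 floor, -8.73, as in the variance-stabilizing transformation of DESeq2. The transformation was inverted and gave whole read numbers for every cell within 0.01, and the inversion was tested on simulated cells. The tables are cumulative, and the last one, with 157 cells and 13866 genes, was used. Another table held the same 157 cells with 9 further columns of another series, which were left out. The first table holds replicate 1 alone under another transformation. Its genotype differences had a Spearman correlation of 0.989 with those of the last table across genes. The design had foreseen 3 replicates. Column names mark replicate 1, but for the other 53 cells they give the genotype and not whether a cell belongs to replicate 2, replicate 3 or both. These cells were treated as 1 second set, which gives 2 sets per genotype and 1 residual degree of freedom. If the second set holds cells of both replicates, the p-values do not measure the spread between all animals.

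C1 cells with at least 1000 detected genes were kept, 67 wild-type and 56 BK5.IGF-1. Genes detected in at least 10% of the kept cells of 1 genotype were tested. Each sample was the mean of its cells' deposited values, since cells are not replicates. limma 3.58.1 with a mean-variance trend was run with the set as a block, and p was adjusted by Benjamini-Hochberg at 0.05. The block came from the table design. Across 6585 genes, the difference between the 2 sets in wild type had a correlation of 0.0015 with that in BK5.IGF-1. The genotypes of a set thus showed no shared deviation for the block to remove, though 2 pairs are few. The prior degrees of freedom were estimated as infinite, so significance rests on the spread pooled over genes. The fit was tested on simulated samples built by redrawing cells of both genotypes of a set together and shifting 200 of 6585 genes. It recovered 51.5% of shifted genes at a difference of 4 (with 13 other calls), 88.5% at 6 (10 other calls), 95.5% at 8 (2 other calls) and 0.5% at 2, and made 0 calls with no shift. A first form of this simulation drew wild-type cells alone, which left many genes without variance, and recovered no shifted gene at any size. It was replaced, so the recovery rates hold for the second form and depend on the estimated prior. In the second form the samples of a set differed by the drawing of cells alone, while the real ones also differed in makeup and detected genes. The 0 calls with no shift therefore do not show how often the fit calls unchanged genes in the real samples. Gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry.

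The deposited 10X files are UMI counts per gene and cell, which the authors made with the tools above, with no normalization. Cells with at least 500 genes and at most 10% mitochondrial UMIs were kept. Scrublet scores were computed with scanpy 1.11.5, but its automatic threshold marked 1 and 0 cells, so the highest-scoring cells were removed at 0.8% per 1000 cells, 72 in the wild-type and 104 in the BK5.IGF-1 library. The libraries were clustered together (Leiden, 2000 variable genes, 20 principal components, 15 neighbors, resolution 0.6). Clusters were named from markers fixed before the data were examined. The scoring rule, which counts undetected markers as 0, and the doublet rule were set after the clusters and scores were seen. A cluster with 13 of 14 endothelial markers stayed unnamed because Glycam1, on the luminal list, led it. Ratios are of summed UMIs scaled to CPM with exact conditional binomial intervals at 95%, shares have exact binomial intervals, and a share of 0 has an upper limit from 3 counts. On simulated libraries, 95.1% of intervals over 6064 genes covered the true ratio. With 1 library per genotype no test was run. List members had at least 5 CPM in 1 library, and 10000 random lists were matched in 20 bins of expression. For cycling shares each cell was thinned to 2500 UMIs, which left out no cell.

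Genes were named by a rule fixed before the data were examined. For the C1 cells it takes up to 12 genes in each direction past the threshold with the same sign in all sets, filled with the smallest p where fewer passed. For the 10X libraries it takes the 10 highest and 10 lowest ratios at 20 or more CPM in 1 library and 50 or more UMIs in all, over all kept cells and within the largest class. Genes of the IGF pathway, keratins 5 and 14 and up to 4 members of each list are also named. Among the genes the rule takes, a single one is left out of the text. Anxa2, and the genes named for edgeR, were added after their values were seen. Gene positions are from the mm10 annotation. The alternatives covered the block, cell and gene filters, scaling, pseudocounts, doublets, clustering and leaving out each set. Added after seeing the data were edgeR 4.0.16 on recovered reads, the C1 results without cells of other types, the comparison of those with basal-like 10X cells, 10X ratios within the largest class and clustering without Igf1. Values were computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2 and R 4.3.3.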

Results

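Single-cell RNA profiles were collected from mammary stem cell preparations of 10-week-old ICR female mice of 2 genotypes: wild type, and BK5.IGF-1, a transgenic line that overproduces insulin-like growth factor 1 (IGF-1). The C1 platform, which captures single cells in a microfluidic chip and sequences their whole transcripts, was used for 6 samples, 3 per genotype. The 10X platform, which counts molecules by unique molecular identifiers (UMIs) from the 3' end, was used for 2 samples, 1 per genotype. The C1 table held 157 cells, which its column names place in replicate 1 (58 wild-type and 46 BK5.IGF-1 cells) and in a second cell set without a replicate number (25 and 28 cells). After a minimum of 1000 detected genes, 43 and 28 cells remained in replicate 1 and 24 and 28 in the second set, with median totals of 2167760, 2376520, 1401930 and 1428010 reads per cell. The 10X libraries held 22580568 UMIs in 3001 wild-type barcodes and 38001401 UMIs in 3602 BK5.IGF-1 barcodes. After filtering, 2926 and 3495 cells remained, with medians of 5795 and 8011 UMIs.

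The transgene's product was examined first. Igf1, the gene for IGF-1, had reads in none of the kept wild-type C1 cells and in most BK5.IGF-1 cells of both sets. It was detected in 0 of 43 wild-type cells of replicate 1, which allows a share of up to 6.98%, and in 0 of 24 of the second set, which allows up to 12.5%. Of the 15 wild-type cells of replicate 1 below the minimum of detected genes, 1 had 5361 Igf1 reads. It was detected in 17 of 28 BK5.IGF-1 cells of replicate 1 (60.7%, exact binomial interval 40.6 to 78.5%) and in 15 of 28 of the second set (53.6%, 33.9 to 72.5%). In the 10X libraries, Igf1 was at 2.62 CPM (UMI counts scaled to a common library total; 57 UMIs) in wild-type cells and 1254 CPM (45344 UMIs) in BK5.IGF-1 cells, a ratio of 479 (95% interval 369 to 632). Basal-like cells, which carry the keratin 5 and 14 program of the outer mammary layer, held most of it in the BK5.IGF-1 library, at 1473 CPM against 0.417 CPM in wild type. In wild type 47 of the 57 UMIs were in fibroblast-like cells, at 71.5 CPM. In BK5.IGF-1 cells of other classes Igf1 reached 384 CPM in fibroblast-like, 149 in luminal progenitor-like, 80.4 in unnamed and 52.2 in hormone-sensing luminal-like cells. Igf1 lies on chromosome 10 at 87858265 to 87937042 of mm10, and counts of this gene do not separate transgene from endogenous transcripts. Intervals of 10X values cover counting error only, and with 1 library per genotype no 10X difference has a replicate check.

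**Figure D1:**
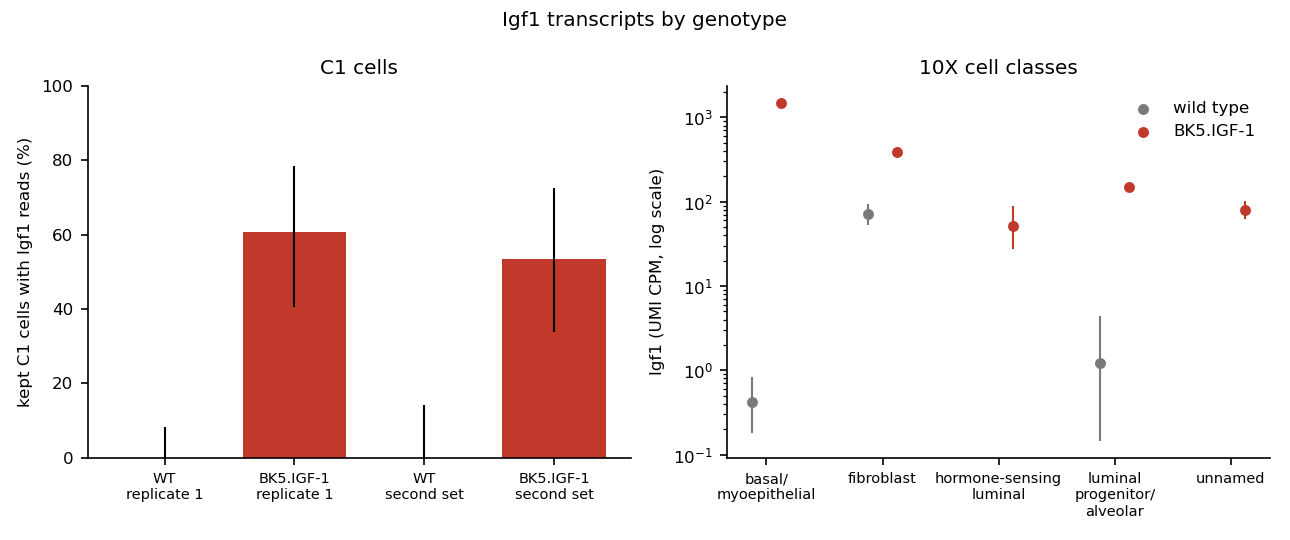
Left, percent of kept C1 cells with Igf1 reads in each sample, as bars with exact binomial 95% intervals as lines. Right, Igf1 UMI CPM (log scale) in each 10X cell class with exact Poisson 95% intervals, classes with no UMI not drawn. BK5.IGF-1 samples (red) reached 60.7% and 53.6% of C1 cells and 1473 CPM in basal-like 10X cells.

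Comparing genotypes in the C1 cells asks which genes of mammary stem cells differ when IGF-1 is overproduced. The glycolytic enzyme genes Tpi1 and Ldha and the hypoxia-responsive genes Ndrg1, Bnip3 and Fam162a rose in BK5.IGF-1 cells. So did Nfkbia, Eno1b, the annexin genes Anxa1 and Anxa2 and the intermediate filament gene Vim. The ferritin gene Fth1, the heme oxygenase gene Hmox1, the Notch ligand Jag1 and the 14-3-3 protein gene Sfn fell. Of 6585 genes tested with limma blocked by cell set (2 sets per genotype), 18 passed an adjusted p of 0.05, 14 higher and 4 lower, each with the same sign in both sets. Of these, Vim, Anxa1, Lgals3, B2m, Fam162a and Sfn did not pass once cells with fibroblast, endothelial or pericyte markers were left out. Differences are given on the log2 scale of the deposited values, whose floor is fixed for all genes, so they follow the share of cells with reads as well as the level and are not folds.

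Among the genes that rose, Igf1 differed most, by 10.61 ± 1.71 (limma SE pooled over genes, n = 2 sets). Ndrg1, a hypoxia-responsive gene, was higher by 10.02 ± 1.87 (chromosome 15, 66929318 to 66969640) and had reads in 71.4% and 75% of BK5.IGF-1 cells against 27.9% and 16.7% of wild-type cells. Nfkbia, the inhibitor of NF-kappaB that its own pathway induces, was higher by 9.58 ± 1.81. The mitophagy gene Bnip3 differed by 8.55, the glycolytic enzymes Tpi1 and Ldha by 8.51 and 6.90, and the hypoxia-responsive Fam162a by 7.67. Eno1b, which is not on the glycolysis list, differed by 7.08. Ahnak differed by 8.14, the galectin gene Lgals3 by 7.53, Vim by 7.43, Anxa1 by 7.34, Anxa2 by 5.11 and B2m, the light chain of MHC class I, by 4.15. Standard errors of the 18 genes ran from 0.51 to 1.87. They rest on the spread pooled over genes, not on the spread of each gene's own sets.

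Among the genes that fell, Sfn differed by -8.84 ± 1.66, with reads in 86% and 100% of wild-type cells and 46.4% in each BK5.IGF-1 set. Jag1 differed by -8.29 ± 1.34 (chromosome 2, 137081456 to 137116644). Hmox1, which encodes heme oxygenase, differed by -4.67 ± 1.16, and Fth1, the ferritin heavy chain, by -2.91 ± 0.51. Further genes were lower in both sets without passing the test: Hspa1b at -4.71, Ptpre at -6.18, Txnrd1 at -5.41, Cald1 at -3.93, Hspb1 at -4.05, Hspa1a at -4.97, Hsp90aa1 at -2.37 and Sdc4 at -1.87, with adjusted p from limma between 0.102 and 0.206. The receptor gene Igf1r was at 0.59, Insr at 2.91, Irs2 at -1.37, Krt5 at -1.01 and Krt14 at -4.63, none past the test. The sets went opposite ways for Krt5 (2.22 in replicate 1 and -4.24 in the second set), Krt14 (1.09 and -10.34) and Igf1r (2.31 and -1.13). The median difference of all genes was 0.95, with 76.6% of genes higher, and 0.34 after rescaling each cell to 1 total. In cells with at least 2000 detected genes it was -0.29, with 45.5% of genes higher. The count was 0 with limma without the block (614 at an unadjusted p of 0.05), 0 with at least 2000 detected genes per cell (167 at that p, 68 higher and 99 lower, against 678 and 53 of 731 at 1000 genes), 1 (Igf1) with no minimum of detected genes, and 5 with edgeR on reads recovered from the kept cells (Igf1, Ackr1, Cd36, Ctla2a and Fabp4). The differences of the 2 sets had a Spearman correlation of 0.10 across genes, which are not independent replicates.

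**Figure D2:**
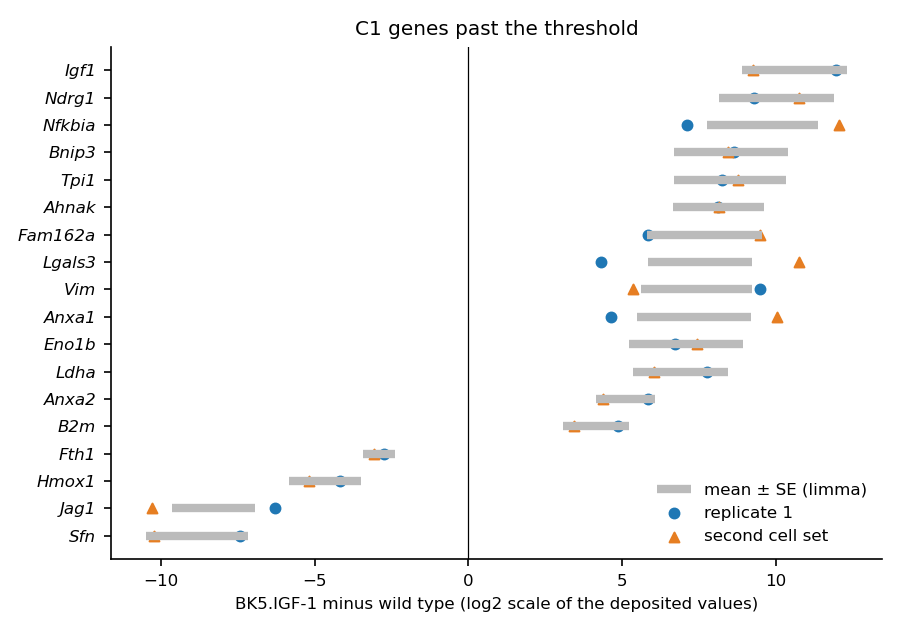
Difference between BK5.IGF-1 and wild-type C1 cells for the 18 genes past the threshold, on the log2 scale of the deposited values. Points are the 2 cell sets and grey bars the mean ± SE from limma, with the SE pooled over genes. Igf1 lies highest at 10.61 and Sfn lowest at -8.84.

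Of 28 gene lists fixed before the data were examined and tested in the C1 cells, glycolysis and hypoxia stood out: all 25 members were higher in BK5.IGF-1, 4 passed the test over all genes and 20 passed adjusted over the list alone, with a median difference of 4.22. Of all 6585 genes tested, 76.6% were higher, so a count of members near that share is no rise of its own. With a preset correlation between genes of 0.01, limma's camera called 9 lists. At a preset correlation its p-values rest on the spread across genes, not on the spread between sets or animals. The 6 that rose were glycolysis and hypoxia (adjusted p 1.2e-16), inflammatory cytokines and chemokines (14 of 15 higher, 5 adjusted over the list alone, median 2.20), interferon response (9 of 10 higher, 4 adjusted over the list alone, median 1.84), unfolded protein response (19 of 21 higher, 6 adjusted over the list alone, median 2.34), IGF axis (10 of 13 higher, 3 adjusted over the list alone) and oxidative phosphorylation (33 of 35 higher, 1 adjusted over the list alone). The IGF axis list includes Igf1 itself, at 10.61, and was not tested without it, so its call is no separate evidence of a response. The 3 that fell were antioxidant and NRF2 targets (14 of 25 lower, 6 adjusted over the list alone, with Txnrd1 at -5.41 and Srxn1 at -5.39), basal and myoepithelial genes (11 of 21 lower, 4 adjusted over the list alone: Jag1, Krt14 and Krt17 lower and Vim higher) and epidermal keratins and differentiation (5 of 9 lower, 1 adjusted over the list alone, Sfn). Krt14 (1.09 in replicate 1 and -10.34 in the second set) and Krt17 (1.04 and -10.07) were lower in the second set alone. With an estimated correlation camera called none of the 9 (adjusted p = 0.735 for each), and fry called none (lowest adjusted p 0.0688). With an estimated correlation camera rested on 1 residual degree of freedom, too few for that check to decide. Glycolysis and hypoxia also lost its call there, at an estimated correlation of -0.04, below the preset 0.01. For that list the loss therefore does not show that correlation between genes removes the call. The estimate was above 0.01 for the basal (0.486), NRF2 (0.0933), oxidative phosphorylation (0.0723) and inflammatory lists (0.0476). For these lists correlation between genes may remove the call. It was at or below 0 for the other called lists.

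Other lists did not pass in the C1 cells, and their counts stand against 76.6% of all genes tested being higher. PI3K-AKT-mTOR genes were higher in 16 of 20 members (none adjusted over the list alone) and MAPK genes in 9 of 19 (1, Ccnd1 at 4.51). Mammary stem cell associated genes split evenly, 8 higher and 8 lower. Luminal progenitor genes were higher in 9 of 10, pan-luminal genes in 12 of 13, hormone-sensing genes in 4 of 6 (2 adjusted over the list alone, Ly6a at 5.44 and S100a6 at 5.02) and mesenchymal transition genes in 12 of 14. Immediate early genes were higher in 20 of 26 (11 passed adjusted over the list alone, 7 higher and 4 lower), and p53 targets and cell cycle inhibitors in 12 of 14 (3, with Plk2 at 6.66 and Cdkn1b at 6.04). G1/S genes split 4 to 4 and G2/M genes were higher in 11 of 13. Basement membrane and matrix genes were higher in 14 of 19, cholesterol genes in 7 of 9, lipid storage genes in 12 of 15, EGF-family genes in 3 of 4, translation factors in 17 of 30 and ribosomal protein genes in 56 of 79, none adjusted over the list alone. Wnt genes were higher in 9 of 12 (1 adjusted over the list alone) and Notch genes in 6 of 9 (2 adjusted over the list alone, 1 higher and Jag1 lower). For mammary stem cell, Wnt, Notch, G1/S, translation factor and ribosomal protein lists, the median was above 0 while camera's direction was down. Camera compares a list with all other genes, whose median was 0.95.

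The makeup of the C1 cells also differed. Reads of 3 or more fibroblast markers were found in 3 of 43 and 0 of 24 wild-type cells and in 4 of 28 and 6 of 28 BK5.IGF-1 cells. For endothelial markers the counts were 0, 0, 4 and 2 in the same order. Cells with 3 or more basal markers were 62.8% and 64.3% in replicate 1 but 95.8% of wild-type and 42.9% of BK5.IGF-1 cells in the second set, and hormone-sensing luminal markers were found in 7.0% and 3.6%, then 0 of 24 and 25% of cells. Jag1, on the basal list, and Sfn were at -6.30 and -7.43 in replicate 1 and at -10.28 and -10.24 in the second set. No C1 test was restricted to basal cells, so these falls were not separated from the lower share of basal cells in the second set. Without cells of fibroblast, endothelial or pericyte markers 14 genes passed, of which 12 were among the 18. Glycolysis and hypoxia, NRF2 targets and oxidative phosphorylation were still called by camera at the preset correlation. With all kept cells, however, camera did not call oxidative phosphorylation without the block (adjusted p 0.110) or with each cell rescaled (0.0669). The pan-luminal (adjusted p 2.9e-06) and luminal progenitor lists (0.00585) were then called as well, but with an estimated correlation (0.436 and 0.394 for these 2) or with fry no list was called (lowest adjusted p 0.799 and 0.120). The check with an estimated correlation again rested on 1 residual degree of freedom and cannot decide. The inflammatory, interferon, unfolded protein, IGF axis, basal and epidermal lists were no longer called at the preset correlation (0.280 to 0.799). Median detected genes per cell were 1370 in wild type and 1844.5 in BK5.IGF-1 for replicate 1, and 1731.5 and 2656 for the second set, a mean difference of 699.5. An exact sign-flip permutation test of the 2 differences, two-sided, gave p = 0.5, the smallest that 2 sets allow.

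The 10X libraries give the genotypes at higher cell numbers, and most cells of both were basal-like. Basal-like cells made up 92.3% of wild-type cells (exact interval 91.2 to 93.2%) and 89.0% of BK5.IGF-1 cells (87.87 to 89.98%). Luminal progenitor-like cells were 3.59% (2.94 to 4.33%) and 6.41% (5.62 to 7.27%), fibroblast-like cells 3.35% and 2.37%, and hormone-sensing luminal-like cells 0.786% and 0.658%. A group of 56 BK5.IGF-1 cells (1.60%) led by Glycam1, with 13 of 14 endothelial markers, stayed unnamed; 0 of 2926 wild-type cells fell in it, which allows a share of up to 0.103%. The group depended on the filter: with the stricter filter, and with doublets kept, its 56 cells joined 74 wild-type and 47 or 53 other BK5.IGF-1 cells in an endothelial-like class (2.56% and 2.98%, and 2.47% and 3.03%). The cells were sorted, and the sort can set these shares. The fibroblast-like class was mixed: at a higher clustering resolution 56 of its 181 cells stayed in it, and 124 formed a cluster with 11 endothelial, 11 basal, 6 fibroblast and 6 pericyte markers. The fibroblast-like shares were then 0.786% of wild-type and 0.944% of BK5.IGF-1 cells, the other direction, as they were with the stricter filter and with doublets kept. Values given for fibroblast-like cells cover both. Basal-like cells of the genotypes lay in different clusters: clusters 0 and 1 were nearly all wild type (1161 and 1477 wild-type cells against 13 and 25) and clusters 6 and 7 nearly all BK5.IGF-1 (1210 and 1796 against 9 and 20), so with 1 library each these clusters may be libraries rather than cell types.

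Within basal-like cells, UMIs of some secreted inflammatory genes were higher in BK5.IGF-1 and those of receptors of the IGF and insulin pathway lower. Besides Igf1, the cytokine genes Il24 and Il19 were 16.7 times (11.9 to 24.2) and 13.8 times (9.86 to 19.8) as high, the matrix protein gene Spp1 7.21 times, the chemokines Ccl2 and Ccl7 4.89 and 4.56 times, and the stress keratin Krt16 4.49 times. Part of these UMIs may come from other cells: Spp1 was at 69.1 CPM in basal-like and 8022 in luminal progenitor-like cells, and Ccl2 and Ccl7 were at 32.9 and 25.9 CPM in basal-like and 7732 and 3047 in fibroblast-like cells. Glycam1 (308 against 0.0521 CPM, 1 wild-type UMI) and the milk protein gene Csn2 (20.1 against 2.14) were also higher. In the same library Csn2 was at 18.5 to 20.1 CPM in fibroblast-like, hormone-sensing and unnamed cells, and Glycam1 at 228 to 371 CPM in fibroblast-like and luminal cells, while luminal progenitor-like cells held 3626 CPM of Csn2 and the unnamed cells 133725 CPM of Glycam1. The chemokine receptor Cxcr4 was lowest at 0.088 (0.066 to 0.116), followed by Fam13a at 0.096, Trp53inp1 at 0.12, Hmga1 at 0.13, Gatsl2 at 0.15, Txnip, an inhibitor of glucose uptake, at 0.214, the thyrotropin-releasing hormone gene Trh at 0.223, Gprin3 at 0.237, Slc43a2 at 0.248 and Dedd2 at 0.277. Igf1r was at 0.485 (0.450 to 0.523), Insr at 0.535, Irs1 at 0.719 and Irs2 at 0.722, while Krt5 and Krt14 were at 1.44 and 1.53. The C1 cells did not show lower receptors: Insr was higher in both sets (1.85 and 3.97) and Igf1r split (2.31 and -1.13). Irs2 was lower there (-1.37), and none of these genes passed the C1 test. Over all kept cells the highest ratios belonged to genes of the unnamed cells (Glycam1 26800, Serpina1b 303, Serpinb1a 81.5, Ubd 43.9, Pf4 35.7, Pglyrp1 17.7), to Igf1 and to the milk protein gene Csn1s2a (103). The lowest over all kept cells included Cxcr4 (0.125), Hmga1 (0.138), Txnip (0.244) and Ramp3 (0.310).

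Gene lists were compared in the 10X libraries by their median log2 ratio and its place among 10000 random lists of matched expression, a description of these libraries. Over all kept cells 14 of 29 lists lay outside the central 95% of random lists, 10 above and 4 below. Those above were inflammatory cytokines (median 0.68), glycolysis and hypoxia (0.63, 24 of 25 members higher), luminal progenitor and alveolar genes (0.62), interferon response (0.40, 20 of 20 higher), cholesterol biosynthesis (0.34), immediate early genes (0.28), EGF family (0.27), unfolded protein response (0.26), translation factors (0.18) and mesenchymal transition genes (0.15). Those below were hormone-sensing luminal genes (-0.38), PI3K-AKT-mTOR genes (-0.21), mitochondrially encoded genes (-0.20) and NRF2 targets (-0.15). The other lists, the cell cycle, Wnt, Notch and MAPK lists among them, lay inside the range. Within basal-like cells, of these 4 the NRF2 targets alone stayed below the range, and the IGF axis (-0.29) and pan-luminal genes (-0.29) lay below it as well. Camera at the preset correlation had called the IGF axis, with Igf1 on the list, as higher in the C1 cells. In basal-like cells the glycolysis and hypoxia list had a median of 0.65, led by the hydroxylase gene Egln3 at 3.36 times, the carbonic anhydrase gene Car9 at 3.00 and Pfkfb3 at 2.30, and the unfolded protein list had Sdf2l1 at 3.04 and Chac1 at 2.28. Ccnd1, a cyclin of G1, was at 3.02, Hbegf at 3.04 and Ereg at 4.50, while stem cell associated Lgr5 was at 0.489 and Aldh1a3 at 0.393, though that list lay inside the random range (median -0.21, 7 of 18 higher). The luminal list includes Csn2 and Glycam1, and the inflammatory list Ccl2 and Ccl7. After thinning to 2500 UMIs per cell, 34.5% of wild-type and 32.5% of BK5.IGF-1 cells had UMIs of at least 3 G2/M genes (78.7% and 89.2% unthinned), and no cycling is read from this.

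**Figure D3:**
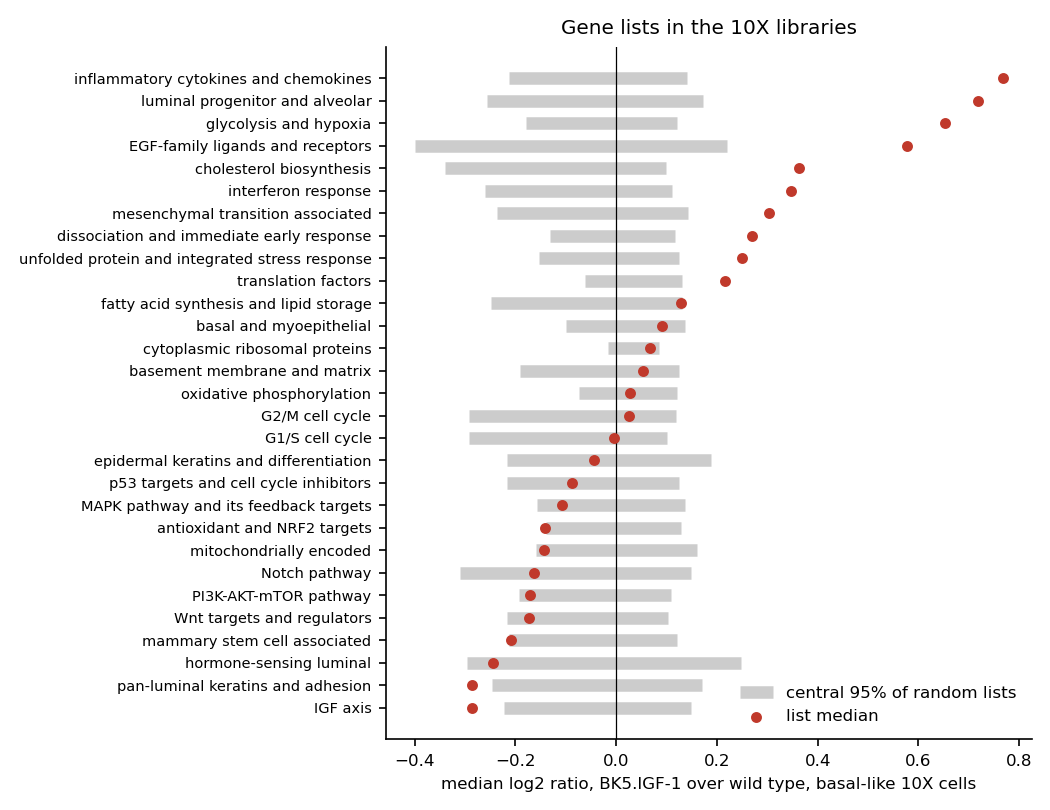
Median log2 ratio (BK5.IGF-1 over wild type) of each gene list in basal-like 10X cells as red points, with the central 95% of random lists of matched expression as grey bars. Glycolysis and hypoxia lies at 0.65 and the IGF axis at -0.29.

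The last comparison asks whether the platforms give genes the same direction. Of the 18 C1 genes past the threshold, 16 had the same direction in basal-like 10X cells, though Eno1b's interval covered 1 (1.09, 0.947 to 1.27) and Anxa1 (1.08) and B2m (1.07) differed little. Igf1, Ndrg1 (1.71 times), Bnip3 (1.69), Ldha (1.61), Vim (1.49), Fam162a (1.47) and Lgals3 (1.43, but 0.924 over all kept cells) were higher there, and Fth1 (0.571) and Hmox1 (0.603) lower. Sfn was higher (2.06) and Jag1 slightly higher (1.07) in the 10X library, against their C1 direction. Across 5046 genes the Spearman correlation of C1 differences with 10X ratios was 0.071 over all kept cells, and across 5018 genes it was 0.037 in basal-like cells. After centring within bins of expression it was 0.065 over all kept cells (shuffled genes gave -0.025 to 0.027). In basal-like cells it was then 0.030 (shuffled genes gave -0.027 to 0.025). With C1 cells of other types left out as well it was -0.022, inside the range of shuffled genes (-0.029 to 0.029). After centring, 51.3% of genes had the same sign on both platforms over all kept cells and 50.6% in basal-like cells. The share was 48.8% in basal-like cells once C1 cells of other types were left out. Genes are not independent replicates, and no p is given.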

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

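The edgeR fit, the results without C1 cells of other types, the ratios within basal-like cells and clustering without Igf1 were chosen after seeing the data. The 18 C1 genes gave 26 calls (18 shared) at a detection filter of 30%, 14 (14 shared) with no detection filter, 20 (17 shared) with each cell rescaled and 20 (14 shared) with no mean-variance trend. None passed without the replicate block (0) or with at least 2000 detected genes per cell (0), 1 passed with no cell filter, 3 (none shared) with log2 of the mean back-transformed value at pseudocount 1 (23, with 5 shared, at pseudocount 0.1), and 5 (1 shared, Igf1) with edgeR; the cause was not tested. Samples share a table, not a labelled animal, and a call lost without the block is not a weaker effect. Across genes, however, the deviations between sets were uncorrelated between the genotypes (0.0015), so the block is not backed by a shared deviation. Leaving out a set leaves no residual degrees of freedom, so it gave values with no test, and the difference in detected genes per cell ran from 474.5 to 924.5; with no cell filter it was 456, with replicate 1 at -40. Replicates 2 and 3 could not be left out singly.

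Some values that passed no test turned sign. Without cells of other types Sdc4 was at 0.25 and Krt5 at 1.37, and with no cell filter Igf1r was at -0.22. With the mean back-transformed value at pseudocounts 1 and 0.1, Irs2 was at 0.45 and 0.46, Krt5 at 1.29 and 1.30, and Krt14 at 0.033 and 0.033; with edgeR Krt5 was at 1.06. Over the named C1 genes, 260 of 375 values kept direction and side of the threshold, 100 lost the threshold and 5 gained it. Of 9 called lists, 0 remained with an estimated correlation (a check on 1 residual degree of freedom, which cannot decide), 0 with fry, and 5 lists were called without cells of other types, of which 3 were shared (glycolysis and hypoxia, NRF2 targets, oxidative phosphorylation). With camera at the preset correlation and no block, oxidative phosphorylation (adjusted p 0.110) and the IGF axis (0.0772) were not called. With each cell rescaled, oxidative phosphorylation (0.0669) and the epidermal list (0.0524) were not called, while the luminal progenitor (0.0400) and pan-luminal lists (0.0186) were.

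For the 10X data, the Igf1 ratio was 3534 within basal-like cells. The basal-like share of BK5.IGF-1 cells was 69.1% at 1000 genes and 5% mitochondrial UMIs, where 690 cells stayed unnamed by the naming rule. Fibroblast-like shares were 0.786% and 0.944% at resolution 1.0, 0.761% and 0.953% with the stricter filter, and 0.734% and 0.917% with doublets kept (wild type and BK5.IGF-1); the last 2 also named an endothelial-like class, 2.56% and 2.98%, and 2.47% and 3.03%. The G2/M share was 78.7% and 89.2% unthinned, 65.3% and 63.1% at 2 genes, and 3.62% and 3.95% at 5 genes. The C1 against 10X correlation was 0.037 in basal-like cells and -0.0077 without C1 cells of other types. Over the alternatives, 23 of 182 ratios of named genes moved beyond their interval and 13 of 116 list medians moved by over 0.1 (a tolerance set after seeing the data).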

Other observations

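The tests below were chosen after the results were seen, except that of a library batch effect alone. Luminal progenitor-like 10X cells carried more transcripts of some milk protein genes in BK5.IGF-1: Csn2 was at 3626 CPM against 594 in wild type, Csn1s1 at 1966 against 500 and Lalba at 247 against 85.0, while Csn3 was at 3390 against 2839 and Wfdc18 at 5278 against 5031. The unnamed BK5.IGF-1 cells had Glycam1 at 133725 CPM and Pecam1, an endothelial adhesion gene, at 787. Ackr1 was at 1665 CPM and Ccl21a at 11578 CPM in these cells, against 241 and 1994 CPM in fibroblast-like BK5.IGF-1 cells. Glycam1 is known from the high endothelial vessels of lymph nodes, while Pecam1 marks endothelium in general, and the labels place the tissue in abdominal and inguinal glands. No wild-type cell fell in this group, but with the stricter filter or with doublets kept it joined an endothelial-like class that held 74 wild-type cells, with 1 Glycam1 UMI among them. No source of these cells was tested.

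Basal-like cells of the 2 libraries lay in separate clusters. Thinning all cells to 1 depth before clustering left 98.3% of basal-like cells in clusters of mostly 1 library, and clustering without Igf1 left 97.7%, which argues against depth and against Igf1 alone as the reason. A batch effect of the library preparation stays open: the correlation of C1 differences with basal-like 10X ratios within expression bins was 0.030, and with 1 library per genotype the batch and the genotype cannot be told apart. The genotype itself is the biological explanation the design offers, and it is untested.

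Glycolysis and hypoxia genes were higher in BK5.IGF-1 on both platforms. Cells of other types do not account for all of the 10X difference, since the list's median log2 ratio was 0.65 within basal-like cells. More genes detected per C1 cell do not account for all of the C1 difference: in cells with at least 2000 detected genes, where the median gene was at -0.29, the list's median was 2.81 with 22 of 25 members higher, against -1.87 to 0.40 for random lists matched on detection. Those cells were few (6 and 5 wild-type, 13 and 20 BK5.IGF-1), and no gene passed the test in them. Their median detected genes were 2811 in wild type and 2294 in BK5.IGF-1 for replicate 1, and 2288 and 2831 for the second set. The gap in detected genes thus turned in replicate 1 and stayed in the second set. A difference in handling between preparations may contribute: immediate early genes, which tissue dissociation induces, had a median of 0.27 in basal-like cells, above random lists, and growth factor signalling induces the same genes, so the explanations cannot be told apart.

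Csn2 and Glycam1 in basal-like BK5.IGF-1 cells may be free RNA. Csn2 was 1.05 times as high in basal-like cells as in fibroblast-like, hormone-sensing and unnamed cells (interval 0.756 to 1.51), and Glycam1 1.22 times as high as in fibroblast-like and luminal cells (1.16 to 1.30), near the like levels that free RNA gives. Igf1 was 11.1 times as high in basal-like cells as in hormone-sensing, luminal progenitor-like and unnamed cells together (10.30 to 11.97), and 3.84 to 28.3 times as high as in single classes, which free RNA alone would not give.

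Spp1 in those cells may be free RNA as well, being 1.07 times as high as in fibroblast-like, hormone-sensing and unnamed cells (0.890 to 1.29). For Ccl2 and Ccl7 this stays open. They were 1.45 (1.20 to 1.77) and 1.51 times (1.21 to 1.89) as high as in hormone-sensing, luminal progenitor-like and unnamed cells together, but hormone-sensing cells had 0 Ccl2 UMIs and Ccl7 was 5.96 times as high as in unnamed cells (2.32 to 21.9).

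One hypothesis was that lower activity of FOXO transcription factors, which insulin and IGF signalling restrains, may account for the lower Igf1r, Insr, Irs2, Trp53inp1 and Txnip of BK5.IGF-1 basal-like 10X cells. A list of 13 other genes known as FOXO targets was written from general knowledge after that pattern was seen, and values or ranks of 5 of them had already been displayed, so the test was run on the other 8. The 6 of these with enough UMIs were all lower, with a median log2 ratio of -0.97 against -0.39 to 0.23 for random lists. The whole list gave -1.16, with 11 of 11 lower, among them the cell cycle inhibitor Cdkn1b at 0.384 times wild type and Ccng2 at 0.380. The C1 cells went the other way: all 8 members tested there were higher, none past the threshold, with a median difference of 1.86 against 0.95 for all genes (76.6% of which were higher), and Cdkn1b was at 6.04 and passed as higher when limma was run with no mean-variance trend. The hypothesis is therefore undecided. Lower RNA of these targets was seen in a single pair of libraries, where batch and genotype cannot be told apart, and the replicated platform did not show it. FOXO activity itself was not measured.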
